A study of Homo sapiens with 192 samples.

How the data were processed

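RNA was measured in 186 single cells and 6 bulk libraries, the latter from 100k cells each, of the prostate cancer lines LNCaP and VCaP. Per the labels, VCaP grew in DMEM and LNCaP in RPMI, both with 10% fetal bovine serum. For the time course, LNCaP cells were kept for 3 days in phenol-red-free RPMI with 10% charcoal- and dextran-stripped serum, were dyed with CellTracker Green or Orange 24 h before treatment, and were collected at 0, 3, 6 and 12 h. The labels give no dose of DHT and name both ethanol and DHT, so whether the 0 h cells received vehicle is not known. Cells were dissociated, and libraries were made with Nextera XT. The FPKM values were computed and deposited by the authors, in 1 column per cell or bulk library and 57424 gene rows. The submitters' processing notes name TopHat2 2.0.6 and the builds hg19 and GRCh37, and the quantifier and the annotation are not given in the sources used here. FPKM cannot be turned back into whole reads, so the depth of each library and the precision it gives are unknown. The number of genes at an FPKM of at least 1 was used in place of depth. An FPKM of exactly 0 may be a gene without reads or a gene without an estimate and is written as listed at 0. No fold against such a value is printed, but with the pseudocount these genes enter rankings, counts and list medians. No coordinates are given, because the reference at hand is of a later build.

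Every cell and bulk library was assigned by its label to 1 of 12 groups, the cells and the bulk library of 6 conditions. No label names separate cultures, so each condition counted as 1 sample, cells were not treated as replicates, and no test, p-value or standard error was computed. There were 6 comparisons: 3, 6 and 12 h each minus 0 h, 6 h minus 3 h, growing LNCaP minus 0 h, and VCaP minus growing LNCaP. For each gene the arithmetic mean and standard deviation of FPKM over cells, the share of cells at an FPKM of at least 1 and the bulk FPKM were computed. Differences are log2(FPKM + 1) of the group means or of the bulk libraries, which understates differences of genes with low values. Shares have exact Clopper-Pearson intervals at 95%, and for a share of 0 the limit is the share that 3 cells would make. Counts of genes at least 2-fold apart come from the 2 bulk libraries of a comparison, over genes at an FPKM of at least 5 in either. The all-gene median was taken over genes at an FPKM of at least 10 in either group.

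A gene was named in a ranking when it was at least 2-fold apart in the same direction in cells and bulk, had an FPKM of at least 5 in the higher group in both, and was detected in at least 25% of the cells of that group. Genes were ranked by the smaller of their 2 differences, and names were taken from the first 12 on each side for 12 h, growing LNCaP and VCaP, 6 for 3 h and 6 h, and 5 for 6 h minus 3 h. Marker genes such as KLK3, MYC and ERG were chosen in advance. Left out of rankings were the 2312 symbols found on several rows, because their values cannot be assigned, small RNAs known by their symbols and mitochondrial genes, because their FPKM depends strongly on length and fragment selection, and sex-linked marker genes, which are not reported. Some ranked genes, among them 1 small nuclear RNA that its symbol did not give away, some list members and 1 list are left out of the text.

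The 28 gene lists, with 707 places, include androgen-induced and androgen-repressed genes, ETS family, G1/S, G2/M, cholesterol and fatty acid synthesis, unfolded protein response, protein secretion and ER transport, polyamine metabolism, steroid metabolism and glucuronidation, immediate-early genes, heat shock, metallothioneins and oxidative stress, p53 targets, glycolysis and hypoxia, interferon response, ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, nuclear long noncoding RNA, luminal and basal epithelium, neuroendocrine, mesenchymal and fibroblast, immune and endothelial genes, apoptosis, and the receptor tyrosine kinase and PI3K pathway. They were assembled from general knowledge of the field, 5 places had no row, and 2 had several. A list result is the median log2 difference of members at an FPKM of at least 1 in either group, set beside 10000 random lists of the same size drawn from 20 expression bins with seed 1. The score of a cell is its mean log2(FPKM + 1) over a list. For the closest condition, each cell's Spearman correlation with each condition's mean log2(FPKM + 1) profile was taken over genes at a mean FPKM of at least 5, leaving the cell out of its own mean.

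The procedure was tested on simulated data with planted 2-, 4- and 8-fold differences. All genes planted at 4- and 8-fold met the naming rule, but only 6 of 34 planted at 2-fold higher and 5 of 33 at 2-fold lower, so rankings and counts that require 2-fold in both kinds of library miss most differences near 2-fold. The planted genes lay well above the naming limits in FPKM and in share of cells. Both simulated groups were drawn from the 0 h cells, and both simulated bulk libraries from the 0 h bulk library with small added noise. Recovery of genes with lower values, or between separately made libraries, was not tested. The alternatives tried were other pseudocounts, filters, scalings, ways of averaging cells, ratios and detection limits, and leaving out low-complexity cells, those with fewer genes than 3 scaled median absolute deviations below their group's median. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.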

Results

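Gene expression was measured in LNCaP and VCaP, established human prostate cancer cell lines, in single cells and in bulk libraries made from a larger number of cells each. The series held 186 single cells and 6 bulk libraries in 6 conditions. LNCaP cells that had spent 3 days in medium with charcoal-stripped serum, which is depleted of steroid hormones, were collected at 0, 3, 6 and 12 h of treatment with dihydrotestosterone (DHT), the main androgen of the prostate. Each of these times had 32 single cells and 1 bulk library. Normally growing LNCaP and normally growing VCaP, both in medium with unstripped serum, had 29 single cells and 1 bulk library each. The labels name ethanol and DHT for the time course without a dose, and list DHT as the treatment at every time, so the 0 h cells are described only by their time. No condition had more than 1 culture that the labels tell apart, and whether the cells and the bulk library of a condition came from the same culture is not known. Each condition therefore counted as 1 sample, no test was made, and every difference below describes the samples at hand.

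The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), from which the depth of a library cannot be recovered. A cell of the 0, 3, 6 and 12 h groups had a median of 8077, 8274.5, 8266 and 8273.5 genes at an FPKM of at least 1, and a growing LNCaP or VCaP cell had 8224 or 7265. The bulk libraries had between 12015 and 12301 such genes, apart from the 12 h bulk library with 9198. Mitochondrially encoded transcripts made up 22.96% of the summed FPKM of the 12 h bulk library, 14.1% of the 0 h bulk library, and a median of 11.04% and 13.2% in the 12 h and 0 h cells. Across genes, which are not independent replicates, the mean over cells and the bulk library had a Spearman correlation of 0.778 at 0 h, 0.803 at 3 h, 0.794 at 6 h, 0.684 at 12 h, 0.785 in growing LNCaP and 0.733 in VCaP. In the text, ± gives the standard deviation among cells, bulk values have no replicate, and intervals of shares of cells are exact 95% Clopper-Pearson intervals for counting error only. A gene was counted as detected in a cell at an FPKM of at least 1. A share of 0 is given with the share that 3 cells would make, which limits the cells in which the gene was detected, not those that express it.

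The time course describes how LNCaP transcripts differed between 0 h and 3, 6 and 12 h of DHT. At 12 h the classical androgen-induced transcripts stood far above their 0 h level in cells and bulk alike. KLK3 (ENSG00000142515.10), which encodes prostate-specific antigen, had a mean FPKM of 9.03 ± 39.5 over the 0 h cells and 292 ± 433 over the 12 h cells, and a bulk FPKM of 25.4 and 375. At 0 h 1 cell at an FPKM of 223 and at 3 h 2 cells at 593 and 617 made up most of the KLK3 means. KLK2 (ENSG00000167751.8), a related kallikrein protease, was at 0.166 ± 0.392 and 47.4 ± 51.2 in the cells and at 1.45 and 63.2 in bulk. FKBP5 (ENSG00000096060.10), a co-chaperone of steroid receptors, was at 2.71 ± 4.76 and 119 ± 102 in the cells and at 6.34 and 77.7 in bulk.

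Gene lists were assembled before the data were examined. Of the 58 androgen-induced genes that could be compared in both kinds of library, 40 were at least 2-fold higher at 12 h than at 0 h in both, and 1, TSC22D3, was at least 2-fold lower in both, being listed at 0 in the 12 h bulk library. The median log2 difference of this list, 12 h minus 0 h, was 1.82 in the cells and 1.51 in bulk, while the median of all genes at an FPKM of at least 10 was 0.18 and 0.13. TMPRSS2, a membrane serine protease, had a log2 difference of 2.31 in the cells and 2.08 in bulk, and NDRG1 3.26 and 2.79. IGF1R, the receptor of insulin-like growth factors, had 4.49 in the cells and 1.47 in bulk. Its bulk values were low, with an FPKM of 2.78 at 12 h and 0.361 at 0 h. The 12 genes that ranked highest by the smaller of their differences were KLK2, ORM1, KLK3, TUBA3D, PGC, FKBP5, EAF2, LPXN, AZGP1, TRPM8, NCAPD3 and AFF3. ORM1, an acute-phase plasma protein, and PGC, a protease precursor, were listed at 0 in all 0 h cells and, like TUBA3D, in the 0 h bulk library, and had a mean of 21.1 ± 43.7 and 12.3 ± 29.9 over the 12 h cells. FOXA1, a pioneer transcription factor of the prostate, lay close together at both times, at 50.6 ± 30.9 in the 0 h cells and 41.7 ± 26.6 in the 12 h cells.

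Androgen-repressed genes lay on both sides of their 0 h level. Of 19 comparable members, 3 were at least 2-fold lower at 12 h in both kinds of library (OPRK1, UGT2B15 and CAMK2N1) and 4 were at least 2-fold higher (SLC15A2, ST6GALNAC1, IGFBP3 and AGR2). OPRK1, the kappa opioid receptor, was at 24.0 ± 34.5 in the 0 h cells and 3.45 ± 8.14 in the 12 h cells, and at 14.7 and 1.204 in bulk. UGT2B15, an enzyme that couples androgens to glucuronic acid, was at 126 ± 294 and 43.7 ± 76.6 in the cells and at 185 and 45.3 in bulk. A 0 h cell at 1443 weighed heavily in the UGT2B15 mean, and without the highest cell of each group the log2 difference was -1.30 instead of -1.50. The list median, 12 h minus 0 h, was -0.51 in the cells and -0.49 in bulk, but it came to -0.05 in the cells when log2 values were averaged over cells and to 0.00 without a filter on low values. OPRK1 also led the 12 genes ranked lowest, followed by SLPI, LINC00648, RP11-1081M5.1, C9orf92, INSIG2, WDR19, MID1, MANEA, LRRN1, USP41 and RALGPS1. Of these, SLPI, LINC00648, RP11-1081M5.1, C9orf92 and RALGPS1 were listed at 0 in the 12 h bulk library. INSIG2, which holds back sterol synthesis, was at 22.4 ± 28.98 in the 0 h cells and 4.79 ± 7.51 in the 12 h cells. MYC was at 42.6 ± 43.7 in the 0 h cells and 24.1 ± 35.8 in the 12 h cells, and at 43.5 and 32.7 in bulk.

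**Figure D1:**
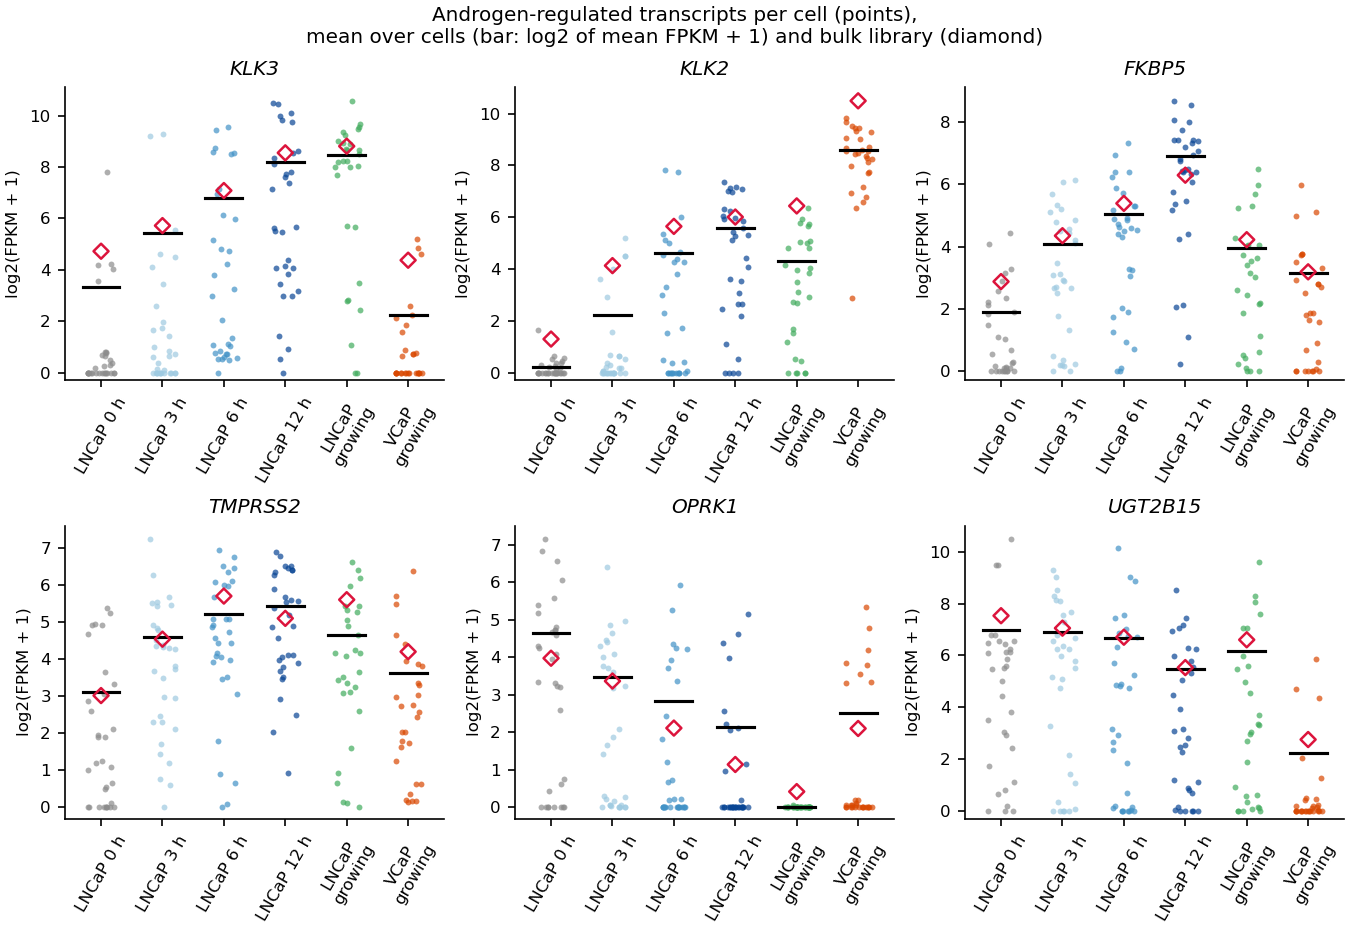
FPKM of 6 androgen-regulated genes on a log2(FPKM + 1) axis in each of the 6 conditions, with 1 point per cell, a bar at the log2 of the mean FPKM + 1 over cells and a diamond at the bulk library. The bars of KLK3, KLK2 and FKBP5 stand higher at 3, 6 and 12 h than at 0 h, and those of OPRK1 stand lower at 6 and 12 h.

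The androgen-induced genes were already higher at 3 h and higher again at 6 h. KLK3 was at 42.0 ± 148 in the 3 h cells and 111 ± 205 in the 6 h cells, and at 51.8 and 135 in bulk. KLK2 was at 3.64 ± 8.34 and 23.3 ± 53.3 in the cells and at 16.5 and 49.0 in bulk. At least 2-fold higher than at 0 h in both kinds of library were 10 of 51 comparable androgen-induced members at 3 h and 24 of 56 at 6 h, and at least 2-fold lower were 0 and 1. The list medians, minus 0 h, were 0.53 in cells and 0.71 in bulk at 3 h, and 0.999 and 1.202 at 6 h. Some genes were still higher at 6 h than at 3 h. The 6 h minus 3 h log2 difference of KLK2 was 2.39 in cells and 1.52 in bulk, and that of TRPM8, a cold-activated ion channel, 2.49 and 1.57.

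At 3 h the genes ranked highest included SGK1, DEFB132, LUZP6 and RP11-701H24.7, the last of which was listed at 0 in the 0 h bulk library. SGK1, a serum- and glucocorticoid-regulated kinase, was at 1.46 ± 5.08 in the 0 h cells and 14.4 ± 18.8 in the 3 h cells, and at 2.95 and 27.1 in bulk. The 6 ranked lowest at 3 h were OSR2, CAPS2, HMBOX1, MLLT3, RP11-483L5.1 and LRRC42, with the log2 difference of OSR2 at -1.44 in cells and -1.13 in bulk. At 6 h the highest included KLK2, PMEPA1, EAF2 and FKBP5, and the lowest were OPRK1, CTD-2541J13.2, MID1, ANKRD28, OSR2 and C5orf30. The ubiquitin ligase gene MID1 was detected in 19 of 32 cells at 0 h and 2 of 32 at 6 h, with bulk values of 17.1 and 4.53. Between 6 h and 3 h the highest were RP11-452L6.7, TRPM8, KLK2, IMMP1L and DLGAP1-AS1, the lowest were LUZP6, RP11-315D16.2, RP11-277L2.5, EPS8 and MCEE, and 9 of 56 androgen-induced members were at least 2-fold higher in both kinds of library, with a list median of 0.48 in cells and 0.53 in bulk. The androgen-repressed list had medians of 0.21 in cells and -0.09 in bulk at 3 h minus 0 h, 0.08 and -0.40 at 6 h minus 0 h, and -0.27 and -0.31 at 6 h minus 3 h.

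Single cells differed widely in these transcripts. KLK3 was detected in 5 of 32 cells at 0 h (15.6%, interval 5.28 to 32.8%), 12 of 32 at 3 h (37.5%, 21.1 to 56.3%), 22 of 32 at 6 h (68.8%, 49.99 to 83.9%) and 29 of 32 at 12 h (90.6%, 74.98 to 98.0%). Counting any FPKM above 0 as detected, the shares were 46.9%, 62.5% and 96.9% at 0, 3 and 6 h. FKBP5 was detected in 14 of 32 cells at 0 h and 31 of 32 at 12 h. A score per cell, the mean log2(FPKM + 1) of the 64 measured androgen-induced genes, had a median of 2.17 at 0 h, 2.73 at 3 h, 2.99 at 6 h and 3.89 at 12 h. Its standard deviation among cells was 0.23 at 0 h and 0.74 at 12 h. Above the highest 0 h cell lay 23 of 32 cells at 3 h (71.9%, interval 53.3 to 86.3%), 23 of 32 at 6 h and 30 of 32 at 12 h (93.8%, 79.2 to 99.2%). When each cell was compared with the mean profile of every condition, 28 of 32 cells at 0 h, 19 of 32 at 3 h, 7 of 32 at 6 h and 24 of 32 at 12 h were closest to their own condition. Of the other 6 h cells, 10 were closest to 3 h, 10 to 12 h, 4 to growing LNCaP and 1 to 0 h. Low-complexity cells, of which there were 4 at 6 h, 1 at 3 h and 0 at 0 h and 12 h, were kept in these counts and mean profiles.

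**Figure D2:**
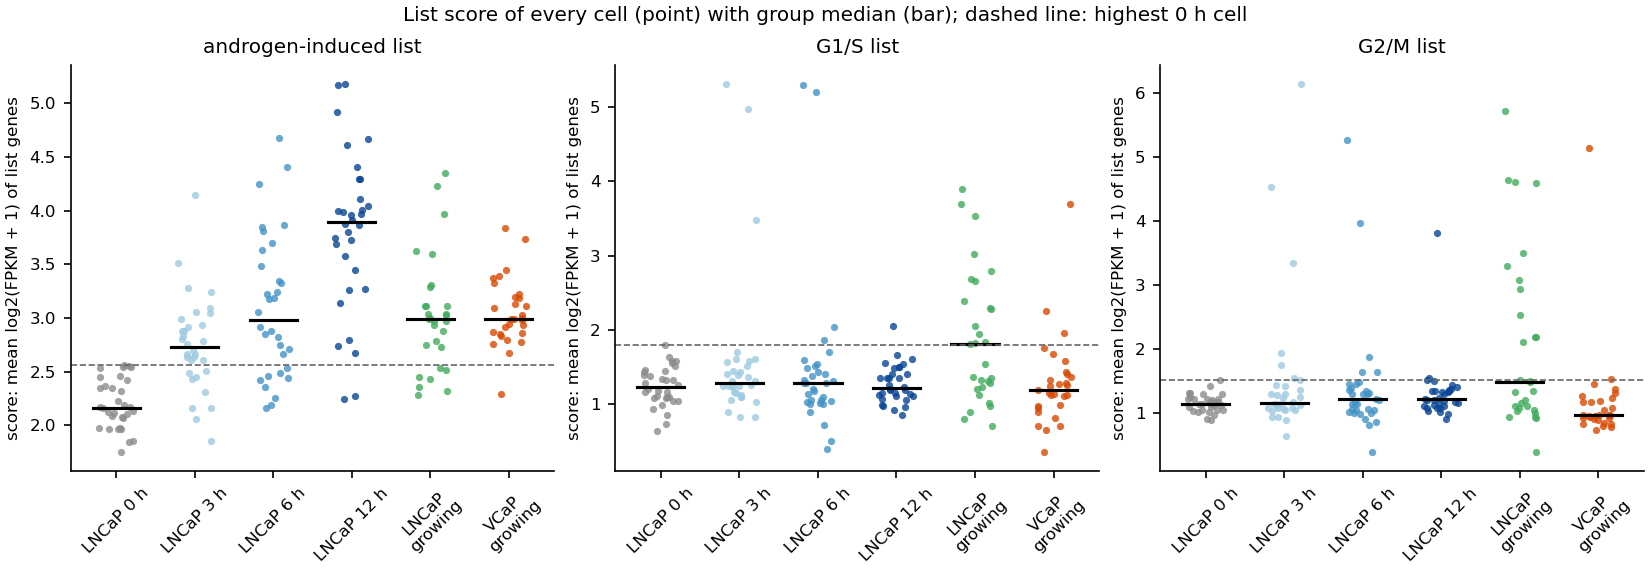
Score of each cell (point), the mean log2(FPKM + 1) over the genes of the androgen-induced, G1/S and G2/M lists, in the 6 conditions, with a bar at the median and a dashed line at the highest 0 h cell. The androgen-induced medians are 2.17, 2.73, 2.99 and 3.89 from 0 to 12 h, and a small number of 3 h and 6 h cells stand far above the rest in the cell-cycle scores.

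Single members of other gene groups differed at 12 h, but no list of this paragraph lay outside the central 95% of matched random lists in both cells and bulk. Of 13 comparable luminal epithelium genes, 5 were at least 2-fold higher than at 0 h in cells and bulk, among them KLK3, KRT19, AGR2 and KRT8, of which KLK3 and KRT19 are also in the androgen-induced list. KRT8, a keratin of luminal cells, was at 154 ± 78.4 in the 0 h cells and 386 ± 277 in the 12 h cells. The endoplasmic reticulum transport list had medians of 0.49 in cells and 0.33 in bulk, with 18 of 25 members higher in both kinds of library, 1 lower in both and 0 at least 2-fold apart. In the unfolded protein response list, with medians of 0.25 and 0.53, the chaperone gene DNAJB9 was at 4.76 ± 6.31 at 0 h and 25.6 ± 25.4 at 12 h in the cells and at 8.80 and 34.3 in bulk. Of 31 sterol and fatty acid synthesis genes, 2 were at least 2-fold higher in both, among them ACSL3, also an androgen-induced member. Of 25 glycolysis and hypoxia genes, 3 were at least 2-fold higher in both, NDRG1, HK1 and PFKP. Of 14 growth factor receptor and PI3K pathway genes, 3 were at least 2-fold higher in both (IGF1R, IGFBP3 and AKT1), and the list medians were 0.39 and 0.34. The bulk FPKM of IGF1R was low at both times.

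Genome-wide, 1769 genes were at least 2-fold higher and 1842 at least 2-fold lower in the 12 h than in the 0 h bulk library, against 420 and 318 at 3 h, 495 and 373 at 6 h, and 300 and 281 between 6 h and 3 h. At 3 h more genes were higher than lower under every setting, with 497 and 468 after rescaling to a common sum, but for the other comparisons the side with more genes depended on the setting. At 12 h the counts were 1677 and 964 among genes above 0 in both libraries, 1417 and 1075 at an FPKM of at least 10, and 1473 and 2567 with values rescaled to a common sum. Rescaling gave 502 and 577 at 6 h and 336 and 424 between 6 h and 3 h. The steroid metabolism list shows the same limit, with a 12 h minus 0 h median of 0.06 in the cells and -1.42 in bulk, which came to 0.06 in bulk among members above 0 in both libraries. The 12 h and 0 h cells share 0 wells of a 96-well plate, as do the 3 h and 6 h cells and the growing LNCaP and VCaP cells. Each of the other 12 pairs of groups shares 8 to 15 wells, and no label names a plate. If each well held a single cell, groups that share wells cannot lie wholly on the same plate. The 3 h, 6 h and growing LNCaP cells would then differ from the 0 h cells at least partly in plate as well.

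**Figure D3:**
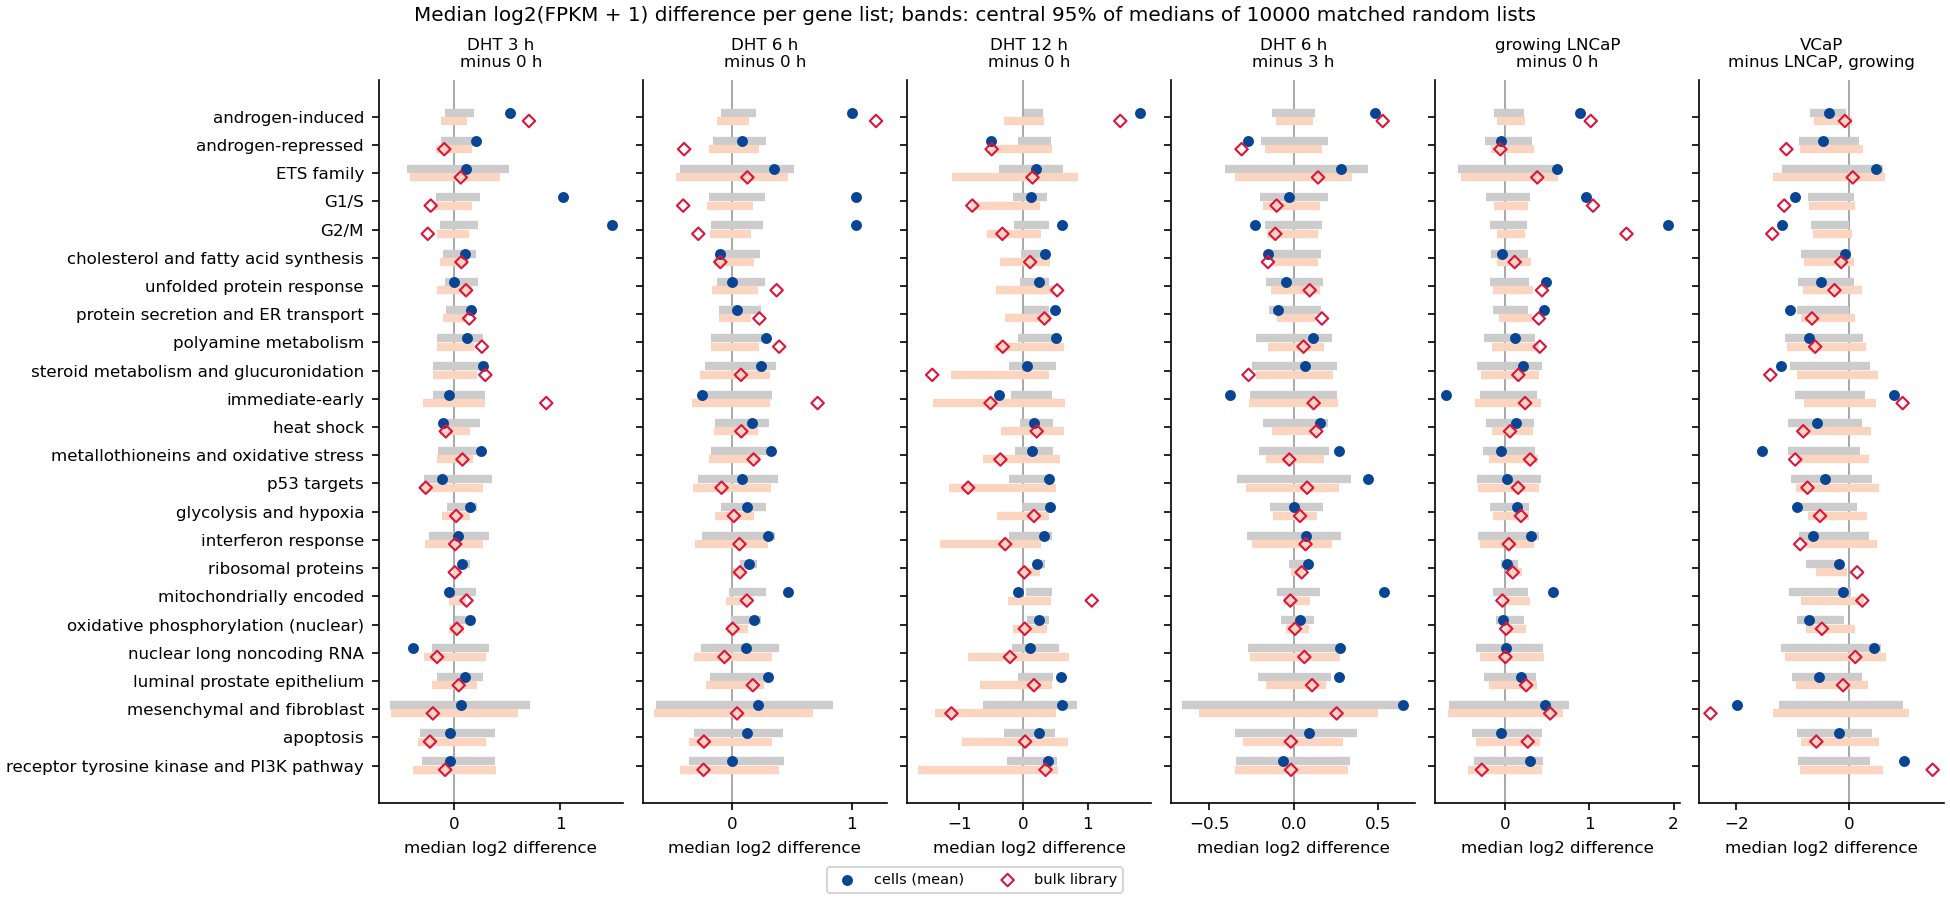
Median log2(FPKM + 1) difference of 24 gene lists in the 6 comparisons, in the mean over cells (blue points) and in the bulk libraries (red diamonds), with bands for the central 95% of 10000 random lists matched in size and expression. The androgen-induced list lies at 1.82 in cells and 1.51 in bulk for 12 h minus 0 h, and the G2/M list at 1.94 and 1.44 for growing LNCaP minus 0 h.

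Growing LNCaP and the 0 h LNCaP cells from stripped serum differed in androgen-regulated and in cell-cycle genes. KLK3 was at 349.9 ± 339 in the growing cells and 449 in the growing bulk library, and KLK2 at 18.9 ± 21.997 and 85.5. Of 55 comparable androgen-induced genes, 20 were at least 2-fold higher in growing LNCaP in both kinds of library and 1, ACPP, was at least 2-fold lower, and the list medians were 0.88 in cells and 1.02 in bulk. Of 52 comparable G2/M genes, 36 were at least 2-fold higher in both and 0 at least 2-fold lower, with medians of 1.94 in cells and 1.44 in bulk. The spindle checkpoint kinase BUB1 was at 7.32 ± 18.1 in the growing cells and listed at 0 in all 0 h cells, and at 34.4 and 4.50 in bulk. Of 43 comparable G1/S genes, 16 were at least 2-fold higher in both and 0 lower, with medians of 0.96 and 1.04, and RAD51AP1, a DNA repair gene, had a difference of 3.90 in cells and 2.25 in bulk. MKI67, a marker of cycling cells, was detected in 12 of 29 growing cells (41.4%, interval 23.5 to 61.1%) and 0 of 32 cells at 0 h, which allows a share of up to 9.38%. With log2 values averaged over cells, the G2/M median was 0.86 and the G1/S median 0.58. Growing LNCaP minus 0 h medians were 0.56 in cells and -0.035 in bulk for mitochondrially encoded genes. Those for immediate-early genes were -0.70 and 0.23. Both lists lay outside the central 95% of matched random lists in the cells but not in bulk. The mitochondrial share of a cell had a median of 14.3% and an upper quartile of 21.4% in growing LNCaP, against 13.2% and 14.2% at 0 h. No cell of these groups was of low complexity, so leaving out such cells could not test the mitochondrial median.

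Genes lower in growing LNCaP than at 0 h included androgen-repressed ones. PLA2G2A, a secreted phospholipase, was at 169.5 ± 564 in the 0 h cells and 1.88 ± 5.95 in the growing cells, and at 179 and 16.9 in bulk. DDC, a decarboxylase that makes dopamine and serotonin, was at 349 ± 456 and 14.1 ± 31.2 in the cells and at 601 and 134 in bulk. The androgen-repressed list as a whole had 6 members at least 2-fold higher (AGR2, BRCA1, ST6GALNAC1, UGT2B28, SLC15A2 and BLM) and 5 lower (ACKR3, DDC, CAMK2N1, PLA2G2A and OPRK1) of 23, with medians of -0.05 and -0.06. In the endoplasmic reticulum transport list 21 of 25 members were higher in both kinds of library and 0 lower, with medians of 0.46 in cells and 0.40 in bulk, among them KDELR2 with 0.67 and 0.78 and SSR1 with 0.62 and 0.69. The 12 genes ranked highest were TRGC1, KLK2, KLK3, TM4SF1, TRIM49D1, TRIM49D2P, BUB1, TRPM8, KLKP1, HIST1H1B, KLK4 and C19orf48. Those ranked lowest included OPRK1, PLA2G2A, IFI27L2, AP004372.1, CAMK2N1, HIST1H4B, MAP1B, DDC, NIPSNAP3A and LINC00648, with HIST1H4B listed at 0 in the growing bulk library. The growing bulk library had 685 genes at least 2-fold higher and 553 at least 2-fold lower than the 0 h bulk library, against 733 and 746 with values rescaled to a common sum, 593 and 591 with median-of-ratios scaling and 1401 and 1430 without a filter. The medium and the serum of the 2 conditions differed together, and the labels name the CellTracker dye for the time course only.

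The comparison of the growing lines describes how VCaP, grown in DMEM, and LNCaP, grown in RPMI, differ. Line and medium differed together, so these data cannot tell their parts in a difference apart. Each line had its own ETS family transcription factor. ERG (ENSG00000157554.14), the partner of the TMPRSS2 fusion known in VCaP, was detected in 29 of 29 VCaP cells (100%, interval 88.1 to 100%) with a mean of 106 ± 72.7 and a bulk value of 46.0, and in 0 of 29 growing LNCaP cells, which allows a share of up to 10.3%. ETV1 (ENSG00000006468.9), known to be rearranged in LNCaP, was detected in 24 of 29 growing LNCaP cells (82.8%, interval 64.2 to 94.2%) with a mean of 59.4 ± 50.03 and a bulk value of 97.7, and in 0 of 29 VCaP cells. No cell of either line had both.

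Androgen-induced genes were split between the lines. Of 59 comparable members, 11 were at least 2-fold higher in VCaP in both kinds of library and 13 at least 2-fold lower, and the list medians were -0.36 in cells and -0.08 in bulk beside a median of all genes at an FPKM of at least 10 of -0.48 and -0.40. KLK2 was at 389 ± 237 in VCaP cells and 18.9 ± 21.997 in LNCaP cells, and at 1439.9 and 85.5 in bulk. KLK3 had the opposite order, at 3.73 ± 9.09 and 349.9 ± 339 in the cells and at 19.8 and 449 in bulk, and was detected in 8 of 29 VCaP cells and 27 of 29 LNCaP cells. ACPP, prostatic acid phosphatase, had a log2 difference, VCaP minus LNCaP, of 4.68 in cells and 4.46 in bulk, TRPM8 of 4.20 and 3.55, SORD of -2.72 and -3.36 and ELOVL5 of -2.40 and -3.20. Androgen-repressed members were split as well, with 9 of 23 at least 2-fold higher and 9 at least 2-fold lower. The glucuronidating enzymes UGT2B15 and UGT2B17 were at 3.70 ± 11.7 and 0.765 ± 3.55 in VCaP cells against 72.1 ± 161 and 91.4 ± 168 in LNCaP cells.

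Neuroendocrine genes were higher and cell-cycle genes lower in VCaP. Of 7 comparable neuroendocrine members, 5 were at least 2-fold higher in both kinds of library (SCG3, UCHL1, CHGB, SCG2 and CHGA) and 0 lower, and SCG3, a secretogranin, was at 22.5 ± 15.4 in VCaP cells and 0.0568 ± 0.227 in LNCaP cells. Of 53 comparable G2/M members, 23 were at least 2-fold lower in VCaP and 0 higher, with medians of -1.18 in cells and -1.36 in bulk, and CDK1, the mitotic kinase, was at 0.514 ± 1.76 in VCaP cells and 28.3 ± 54.5 in LNCaP cells. The G1/S medians were -0.95 and -1.15, with 15 of 42 members at least 2-fold lower and 1 higher. The mesenchymal markers VIM, FN1, ACTA2 and TWIST1 were at least 2-fold lower and LUM at least 2-fold higher, among 6 comparable members. The medians of the mesenchymal and fibroblast list were -1.99 in cells and -2.45 in bulk, but 0.71 in cells at an FPKM of at least 10. Of 17 receptor tyrosine kinase and PI3K pathway genes, 6 were at least 2-fold higher in both (among them IRS2, IGFBP3, IGF1R and SPRY1) and 3 lower (ERBB2, PIK3R1 and ERBB3). Of 21 interferon-response genes, 9 were at least 2-fold lower and 1, PSMB8, higher. The interferon-response medians of -0.65 in cells and -0.87 in bulk came to -0.03 in bulk with median-of-ratios scaling.

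The 12 genes ranked highest in VCaP were ITM2A, NPY, ADIRF, SCGN, NAALAD2, TRGV9, S100A10, RP11-250B16.1, TSPAN8, HGF, SHH and MT1E, of which ITM2A, NPY, ADIRF, SCGN, S100A10, RP11-250B16.1, HGF, SHH and MT1E were listed at 0 in LNCaP bulk. NPY, a secreted neuropeptide, was at 2869.7 ± 3248 in VCaP cells and 4794 in VCaP bulk, against 2.48 ± 8.37 and a listed 0 in LNCaP. The signalling proteins HGF and SHH were detected in 11 of 29 and 17 of 29 VCaP cells and in 0 of 29 LNCaP cells. The 12 ranked lowest were GAGE12B, GAGE12I, NCAM2, GAGE12G, MT1G, GAGE12F, EFNA5, GAGE2C, GAGE2D, BNIP3L, MAGEA2B and CSAG1, of which GAGE12B, MT1G, GAGE2D, BNIP3L, MAGEA2B and CSAG1 were listed at 0 in VCaP bulk. Copies of the GAGE genes are nearly identical in sequence, so how reads were divided among them is uncertain. NCAM2, a neural cell adhesion molecule, was at 122 ± 98.8 in LNCaP cells and 0.0563 ± 0.0739 in VCaP cells. In bulk, 1383 genes were at least 2-fold higher and 2405 at least 2-fold lower in VCaP, and median-of-ratios scaling gave 2023 and 1656. All 29 VCaP cells and 27 of 29 growing LNCaP cells were closest to their own mean profile. The Spearman correlation between cell and bulk differences across genes, which are not independent, was 0.837. Within LNCaP it was much lower, at 0.135 for 3 h, 0.306 for 6 h and 0.284 for 12 h, each minus 0 h. For 6 h minus 3 h it was 0.173, and for growing LNCaP minus 0 h 0.474.

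**Figure D4:**
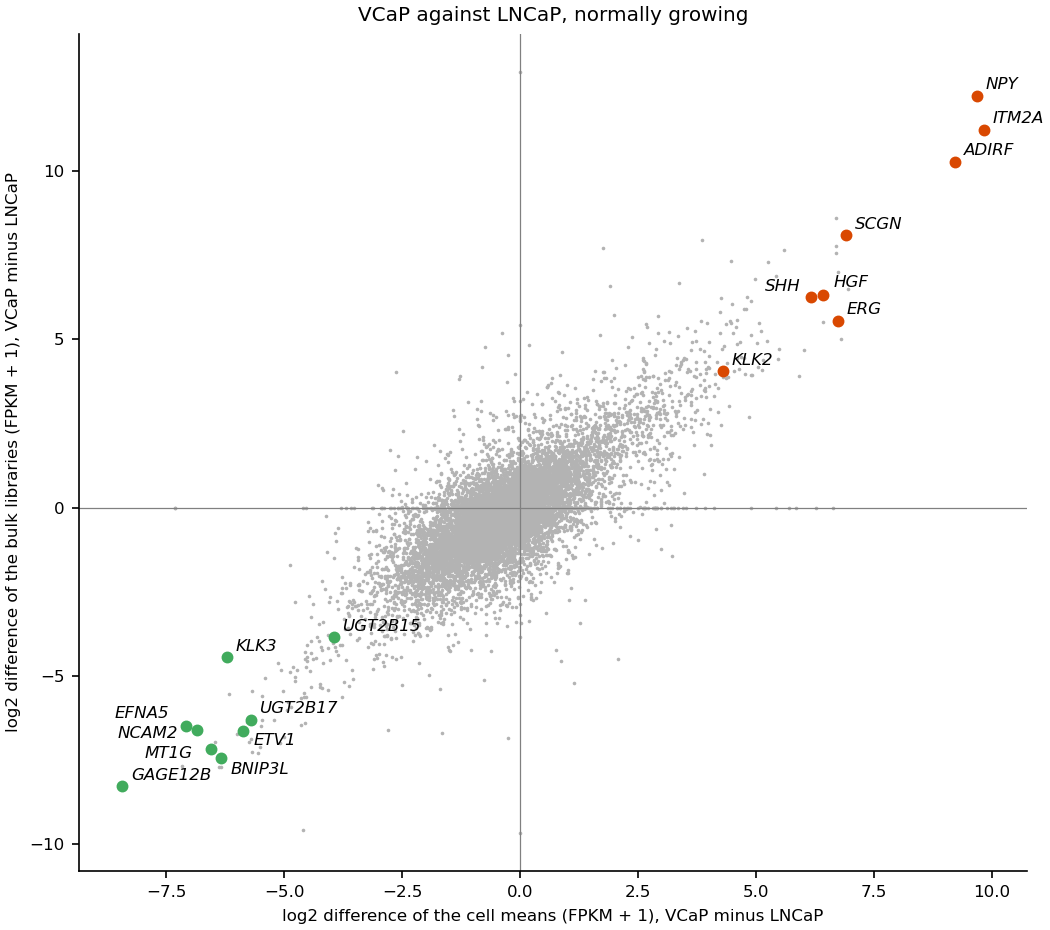
Log2 difference of FPKM + 1, VCaP minus LNCaP, in the means over cells (horizontal) and in the bulk libraries (vertical), with 1 grey point per gene and named genes in orange (higher in VCaP) and green (lower in VCaP). KLK2 lies at 4.29 and 4.06 and KLK3 at -6.21 and -4.44 on the horizontal and vertical axis.

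The cell-cycle lists differed between cells and bulk during the time course. In the 3 h cells the G1/S median, minus 0 h, was 1.02 and the G2/M median 1.49, while the bulk medians were -0.22 and -0.24. In the 6 h cells they were 1.04 and 1.04, with -0.41 and -0.28 in bulk. MKI67 was detected in 0 of 32 cells at 0 h, 5 of 32 at 3 h (15.6%, interval 5.28 to 32.8%), 5 of 32 at 6 h and 2 of 32 at 12 h. The G2/M score exceeded that of the highest 0 h cell in 6 of 32 cells at 3 h (18.8%, interval 7.21 to 36.4%), 5 of 32 at 6 h and 2 of 32 at 12 h, and in 13 of 29 growing LNCaP cells (44.8%, 26.4 to 64.3%). At 12 h the G1/S medians were 0.12 in cells and -0.80 in bulk and the G2/M medians 0.60 and -0.33. Immediate-early genes, which respond within minutes to growth factors and stress, had medians at 3 h minus 0 h of -0.05 in cells and 0.87 in bulk, and at 6 h of -0.25 and 0.71. FOS was at 209 ± 177 in the 0 h cells and 181 ± 134 in the 6 h cells, and at 54.6 and 137 in bulk. The mitochondrially encoded list was 0.46 at 6 h minus 0 h in the cells and -0.02 without the low-complexity cells.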

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

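No paired analysis was possible because each condition was 1 sample and no test was made. The alternatives change a setting of the same samples, and for moved values the cause was not tested. Chosen after seeing the data were the genes and members above 0 in both libraries, the members above 0 in the 12 h bulk library, the data without the VCaP cell that holds the largest value, and all alternatives for named genes. A list median was taken to stay when it moved by less than the distance from the center to the edge of its band of random lists, a bulk gene count within a factor of 1.5, a share of cells within its 95% interval, a correlation or score within 1 standard deviation among conditions or cells, and a named gene on its side of a 2-fold difference, or, below that, within a log2 value of 1. Of the alternative values, 128 of the main list medians, 2019 of the other list medians, 53 bulk gene counts and 2044 values of named genes stayed within these tolerances, while 42, 127, 43 and 68 moved. Of the remaining results 34 stayed and 17 moved. A count that stayed can still change sides, as the counts of 2023 higher and 1656 lower in VCaP with median-of-ratios scaling did. The number of cells closest to their own condition was 25 to 29 of 32 at 0 h and 7 to 9 of 32 at 6 h, depending on the genes used.

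Among list medians outside their band of random lists, the direction turned in 7 of the alternative values. Changes of sign of medians inside the band were not counted. Some of those medians lay close to 0, such as that of ribosomal proteins, 12 h minus 0 h in bulk, at 0.014. The 7 therefore do not show how often a direction turned among all lists. The mitochondrially encoded median, 6 h minus 0 h in cells, was -0.020 without low-complexity cells, against 0.46. The steroid metabolism and glucuronidation median, 12 h minus 0 h in bulk, was 0.11 with an FPKM of at least 10 in either group and 0.062 for members above 0 in both libraries, against -1.42. For VCaP minus LNCaP in cells, the steroid metabolism median was 0.092 and the mesenchymal and fibroblast median 0.71 with an FPKM of at least 10, against -1.21 and -1.99, and the ribosomal protein median was 0.067 with values rescaled to a common sum and 0.23 with median-of-ratios scaling, against -0.18.

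With a pseudocount of 0.1 FPKM the androgen-induced median was 1.15 in cells and 1.54 in bulk at 6 h minus 0 h, 2.01 in cells at 12 h minus 0 h and 0.64 in bulk at 6 h minus 3 h, and in growing LNCaP minus 0 h the cell medians were 1.31 for G1/S and 3.23 for G2/M. With a pseudocount of 5 FPKM the androgen-induced medians were 0.38 in cells and 0.39 in bulk at 3 h, 0.63 and 0.80 at 6 h, 1.21 and 1.15 at 12 h, 0.34 in bulk at 6 h minus 3 h, and 0.64 and 0.71 in growing LNCaP. The androgen-repressed median at 12 h in cells was -0.24, and in growing LNCaP the G1/S medians were 0.54 in cells and 0.66 in bulk and the G2/M medians 1.06 and 1.07.

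Without a filter on low values the androgen-induced median was 0.53 in bulk at 3 h, 0.84 in cells at 6 h and 1.66 in cells at 12 h, and the androgen-repressed median in cells at 12 h was 0. With an FPKM of at least 10 the androgen-induced bulk median was 1.34 at 6 h, 1.29 in growing LNCaP and -0.53 in VCaP minus LNCaP, and the G1/S medians in growing LNCaP were 1.24 in cells and 1.26 in bulk. The value of interferon response, median log2 difference, VCaP minus LNCaP, growing, cells was -1.53. With values rescaled to a common sum the androgen-induced median in cells at 6 h minus 3 h was 0.35 and the interferon response median of VCaP in bulk -0.24. With median-of-ratios scaling the androgen-induced median in cells was 1.66 at 12 h and -0.016 in VCaP minus LNCaP. The value of interferon response, median log2 difference, VCaP minus LNCaP, growing, bulk was then -0.029. Averaging log2 values over cells gave 0.80 at 6 h and 1.63 at 12 h for the androgen-induced list, -0.051 for androgen-repressed, median log2 difference, DHT 12 h minus 0 h, cells, and 0.58 and 0.86 for G1/S and G2/M in growing LNCaP. Without the highest cell of each gene the last 2 were 1.28 and 1.68.

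Counts of genes at least 2-fold higher and lower in bulk moved with the filters. With a pseudocount of 5 FPKM they were 178 and 106 at 3 h, 252 and 141 at 6 h, 134 and 97 at 6 h minus 3 h, and 322 and 251 in growing LNCaP. Without a filter they were 1217 and 1058 at 3 h, 1284 and 1110 at 6 h, 988 and 972 at 6 h minus 3 h, 1401 and 1430 in growing LNCaP and 2802 and 3732 in VCaP, with 4681 lower at 12 h. At an FPKM of at least 10 they were 213 and 149 at 3 h, 286 and 199 at 6 h, 162 and 125 at 6 h minus 3 h, and 427 and 303 in growing LNCaP, with 1075 lower at 12 h and 892 higher in VCaP. At a ratio of 3 they were 169 and 121 at 3 h, 233 and 122 at 6 h, 119 and 115 at 6 h minus 3 h, 246 and 221 in growing LNCaP and 902 and 1248 in VCaP, with 1033 higher at 12 h. Rescaled to a common sum, 577 were lower at 6 h and 424 at 6 h minus 3 h. Among genes above 0 in both libraries, 964 were lower at 12 h, and among members above 0 in the 12 h bulk library 0 androgen-induced members were at least 2-fold lower.

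The Spearman correlation across genes of cell mean and bulk, for genes at an FPKM of at least 10, was 0.69 at 0 h, 0.72 at 3 h, 0.70 at 6 h, 0.59 at 12 h, 0.69 in growing LNCaP and 0.62 in VCaP. Without a filter it was 0.84 at 0 h, 0.85 at 6 h, 0.84 in growing LNCaP and 0.82 in VCaP. The share of cells with KLK3 above 0 was 46.9% at 0 h, 62.5% at 3 h and 96.9% at 6 h, and with KLK3 at an FPKM of at least 10 it was 18.8% at 3 h, 46.9% at 6 h and 10.3% in VCaP.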

Other observations

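Members of further gene groups differed between the growing lines. In VCaP minus LNCaP the steroid metabolism and glucuronidation list had 3 of 15 members at least 2-fold higher in cells and bulk, AKR1C3, HSD17B6 and HSD17B11, and 8 lower. AKR1C3, which makes testosterone from androstenedione, had a log2 difference of 4.76 in cells and 3.96 in bulk. The immediate-early medians were 0.80 and 0.94, but only 4 of 17 comparable members were at least 2-fold higher in both, among them EGR1 at 3.29 and 3.65, and 2 were at least 2-fold lower. Of 24 ER transport members 11 were at least 2-fold lower and 0 higher. The metallothionein and oxidative stress medians were -1.55 and -0.96, with the quinone reductase NQO1 at -6.18 in cells and -5.54 in bulk. The glycolysis and hypoxia medians were -0.92 and -0.52. Medians for heat shock were -0.57 and -0.81, for p53 targets -0.42 and -0.74, for polyamine metabolism -0.71 and -0.60, for oxidative phosphorylation -0.71 and -0.48, and for apoptosis -0.19 and -0.58. These last 5 lists lay within the central 95% of matched random lists in cells and bulk, beside an all-gene median of -0.48 and -0.40.

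For VCaP minus LNCaP the ETS family medians were 0.48 and 0.06, those of cholesterol and fatty acid synthesis -0.08 and -0.14, of the unfolded protein response -0.50 and -0.26, of mitochondrially encoded genes -0.10 and 0.23, of nuclear long noncoding RNA 0.44 and 0.11, and of luminal epithelium -0.53 and -0.11. CD44, one of the 2 basal genes at least 2-fold higher in VCaP among 3, was at 18.02 in VCaP bulk and 0.205 in LNCaP bulk. Immune and endothelial genes were comparable for 1 member in VCaP minus LNCaP and for 0 in 12 h or growing LNCaP minus 0 h. The ribosomal protein medians of -0.18 and 0.14 lay above the central 95% of matched random lists in both kinds of library, and the androgen-repressed median of -1.11 below it in bulk, though not that of -0.46 in cells.

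Of the tests below, all except that of the mitochondrial share were chosen after the result was seen. The G1/S and G2/M lists were higher in the 3 h and 6 h cells than in the 0 h cells, but not in bulk. A small number of cycling cells among those sampled may account for the cell medians, since averaging log2 values over cells kept at most 31.5% of any of them. The same averaging also lowered these medians in growing LNCaP, where 13 of 29 cells exceeded the highest 0 h G2/M score. It therefore separates few cycling cells from many only in part. The difference of cells from bulk within a condition may matter too. Its medians were -1.35 for G1/S and -1.76 for G2/M at 0 h, against -0.15 and -0.27 at 3 h and -0.08 and -0.54 at 6 h. At 12 h they were -0.68 and -0.94, in growing LNCaP -1.45 and -0.89 and in VCaP -1.25 and -1.01. The 0 h cells were thus lowest for G2/M but not for G1/S. For both lists the cells lay least below bulk at 3 h and 6 h. Higher cell-cycle transcripts in the whole treated cultures stay open, because the highest bulk median of -0.22 is part of the pattern itself and rests on 1 bulk library at each time. A difference between plates stays open as well, since no label names plates and the largest median between groups that share no well was 0.60 in size.

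The 12 h bulk library had 1842 genes at least 2-fold lower than the 0 h bulk library. The larger mitochondrial share is argued against, as it would lower the other genes by a log2 value of only -0.16. Lower levels in the whole treated culture are argued against for the 1479 of these genes with a mean FPKM of at least 5 in the cells. Their median difference was -2.13 in bulk but 0.0022 in the cells, with quartiles of -0.46 and 0.35. This holds only if the cells stand for the culture of the bulk library, which the labels do not say. A cell median near 0 is also not special to 12 h, since it was -0.0070 for genes lower in the 3 h bulk library and -0.19 at 6 h. In growing LNCaP it lay further below 0, at -0.65, with 76.2% of such genes lower in the cells. A library of low complexity may account for part of the lower genes. Of the genes with a mean FPKM of at least 10 over cells, 9.91% were listed at 0 in the 12 h bulk library, against 2.73 to 4.27% in the other 5 conditions. Of the 1842 lower genes 964 were above 0 in both libraries.

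Immediate-early genes were higher in the 3 h and 6 h bulk libraries than at 0 h, but not in the cells. A fixed difference between the cell and bulk methods would be the same in every condition, and the pattern itself already departs from that. Over the 5 conditions other than 12 h, the cells minus bulk median had a range of 1.52, from 1.64 at 0 h to 0.12 in growing LNCaP. The limit for matched random lists was 0.79. The 12 h median, left out of the range, was 1.77, above that of 0 h, but it rests on the 12 h bulk library with its many genes listed at 0. The range cannot test the explanation further, because its upper end, 0 h, is the value that defines the pattern. The medians at 3 h and 6 h were 0.75 and 0.40. Handling of the cells before lysis stays open. The excess of 0.89 at 0 h over 3 h, the higher of the medians at 3 h and 6 h, restates the pattern. The medians of growing LNCaP, 0.12, and VCaP, 0.18, lay at percentiles 88.2 and 95.7 of matched random lists and so did not stand out as at 0 h. Higher levels in the whole treated cultures stay open too, since the higher of the 2 cell medians, -0.047, decides nothing while handling may have raised these genes at 0 h. These last 2 explanations cannot be told apart with these data.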
